A study of Caenorhabditis elegans with 8 samples.

How the data were processed

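The series holds RNA-seq of whole worms of 4 Caenorhabditis elegans genotypes: wild type (N2), daf-2(e1370), which lowers the function of the insulin/IGF-1 receptor, hel-1(gk148684), a mutation in a DEAD-box RNA helicase gene, and the hel-1;daf-2 double mutant. Each genotype has 2 libraries, described by the labels as independent biological repeats of day 1 adults grown at 20 °C. All 8 libraries were used, and replicates 1 and 2 of different genotypes were not paired. The wild-type libraries are the control of daf-2 and of hel-1, and the daf-2 and hel-1 libraries are each the control of the double mutant.

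The values are RSEM expected counts per gene, as deposited by the submitters and per the file headers, 1 file per library. RNA was extracted with a phenol-based reagent and sequenced on an Illumina HiSeq instrument, per the labels. The submitters' processing notes name FastQC, cutadapt, TopHat2, Bowtie, HTSeq, edgeR and RSEM 1.3.1 and the builds WBcel235 and ce11. Which aligner fed the counts, and whether counting used strand, is not given in the sources used here. The reads were not analysed here.

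Expected counts were rounded to whole numbers; between 2.03 and 2.79% of the values per library were not whole. Of 46904 genes in the files, 13722 passed edgeR's filterByExpr and hold at least 99.9% of each library's counts. Of the gene identifiers, 46817 are in the WBcel235 annotation and 87 are not, and 44017 carry a symbol there. The libraries hold 36372100 and 34231100 counts (wild type), 31860500 and 35788500 (daf-2), 37552500 and 32417500 (hel-1) and 33271400 and 31555400 (hel-1;daf-2), rounded to 6 digits. The common biological coefficient of variation was 0.168 and the fit had 4 residual degrees of freedom, shared by the 4 groups.

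Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and 1 model of 4 group means over all 8 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05 in each comparison. Adjusted p-values of genes are from this test unless another tool is named. The comparisons are daf-2 with wild type, hel-1 with wild type, hel-1;daf-2 with daf-2, and hel-1;daf-2 with hel-1. The interaction is the hel-1 effect in the daf-2 background minus the hel-1 effect in the wild-type background, on the log2 scale. Values after ± are standard errors for log2 fold changes and standard deviations of 2 libraries for levels in CPM (counts scaled by edgeR to the size of the library).

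The lists of genes to be read as groups, 40 in all, were fixed before the data were examined, as were the comparisons, tests, rule for named genes and most of the other settings tried. The lists of DAF-16-activated and DAF-16-repressed genes were written from earlier work on daf-2 and daf-16 mutants. The list of mitochondrially encoded genes is all genes of the mitochondrial chromosome in the annotation. Some names fixed in the lists are absent from the annotation, hsp-16.11, hsp-16.49, dod-8, dod-16, sodh-1 and daf-21 among them, and were left out. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each was tested again with the correlation estimated from the residuals and with fry. A list "rose" or "fell" where camera with the preset correlation passed 0.05; its members are counted by their own tests over all genes, and again with adjustment over the list alone.

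Genes were named by this rule: hel-1, daf-2 and daf-16 in each comparison; up to 6 called genes per direction with the largest fold changes, at least 5 CPM in the higher group and no overlap between the libraries compared (the last condition was dropped for the interaction); and up to 4 members with the smallest adjusted p from each called list and from the DAF-16 lists, or the 2 best expressed members where none passed. Exceptions, chosen after their values were seen, are myo-1 in daf-2, the genes of 1 stretch of chromosome V, and the genes of 1 window of the hel-1 comparison. Also outside the rule are sod-3, dod-6 and lys-7 in hel-1;daf-2 against daf-2. Where the lower group has no counts, "at least" gives the ratio of the mean CPM to the mean CPM of a floor of 3 counts per library; where it has 1 to 3 counts in total, the ratio is given with its counting interval.

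Counts of genes that share exons cannot be split here. Among the named genes, acdh-2, gst-4, gpd-2, col-116, pbs-7, syp-1 and C05D12.3 share at least 20 exon bases with another gene on the same strand. Others, such as sod-3, fat-5, warf-1, ins-10, saeg-1, ctg-1, lsy-27 and mec-17, share them with a gene on the other strand, whose reads cannot be told apart without strand. Vitellogenin and histone genes have near-identical copies and their values are uncertain.

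The pipeline was tested on simulated data with 50 genes changed per fold. The changed genes were drawn from those with a mean of at least 1 CPM, and each gene had the same dispersion in all groups. The simulations therefore do not hold the wider gap between the daf-2 replicates. In the layout of daf-2 with wild type edgeR recovered 30 of 50 genes changed 2-fold, 42 of 50 changed 4-fold and 50 of 50 changed 8-fold. In that of hel-1;daf-2 with daf-2 it recovered 36, 46 and 48. Of the unchanged genes, edgeR called 12 in the first layout and 22 in the second, and DESeq2 29 and 47. The alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter of 1 CPM in 4 libraries, a replicate block, a fit of only the 2 groups compared, and leaving out each library in turn. After the files were seen, 2 were added: list values without daf-2 replicate 2 set beside those of all libraries, and the signs of the hel-1 effects under each setting. The lone library left in a group is then assumed to vary like those of the other groups.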

Results

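Within each genotype the 2 libraries correlated at r = 0.996 in wild type, 0.987 in daf-2, 0.996 in hel-1 and 0.998 in hel-1;daf-2, over log2 of CPM plus 1 of the tested genes. The standard deviation of the log2 difference between them was 0.258, 0.446, 0.221 and 0.183 in the same order. In daf-2, replicate 2 had higher levels than replicate 1 of sperm genes (median log2 difference 1.61), pharynx markers (1.39), neuropeptides (1.37), collagens (1.32) and body wall muscle markers (0.76). Its oocyte and germline genes (-0.30) and vitellogenins (-0.79) were lower, and its intestine markers stood at 0.01. The pharyngeal myosin gene myo-1 had 2.96 CPM in daf-2 replicate 1 and 55.2 CPM in replicate 2. In wild type, sperm genes stood at -1.85 and collagens at -0.62 in replicate 2 relative to replicate 1.

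**Figure D1:**
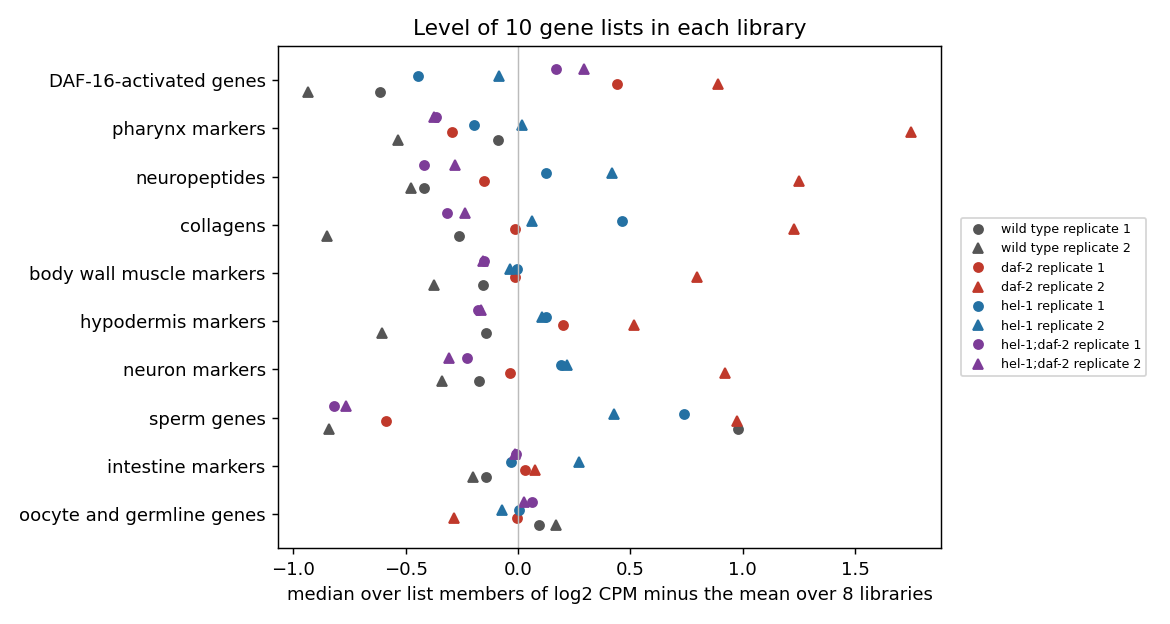
Median log2 CPM of 10 gene lists in each library, relative to the mean of the 8 libraries. Circles, replicate 1; triangles, replicate 2.

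The transcript of hel-1 did not pass the test in any comparison: 610 ± 12 CPM in wild type, 508 ± 56.3 in daf-2, 545 ± 27.8 in hel-1 and 531 ± 6.5 in hel-1;daf-2, with a log2 fold change of -0.16 ± 0.10, adjusted p = 0.521 in hel-1. Gene counts do not show the hel-1 lesion itself. daf-2, which encodes the insulin/IGF-1 receptor, rose in the daf-2 mutant (0.33 ± 0.08, adjusted p = 0.0308), from 113 ± 5.07 to 142 ± 4.06 CPM; the call ended with any 1 of the wild-type, hel-1 or hel-1;daf-2 libraries left out. daf-16, the FOXO transcription factor downstream of the receptor, stood at 0.03 ± 0.09 in daf-2 (adjusted p = 0.844) and -0.05 ± 0.09 between hel-1;daf-2 and daf-2 (adjusted p = 0.741).

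In daf-2 worms the DAF-16-activated genes rose together: of 39 measured, 27 rose, 0 fell and 12 did not pass (median 1.54, camera adjusted p = 1.3e-21, adjusted p = 0.688 with an estimated correlation). sod-3, a mitochondrial superoxide dismutase, rose 18-fold, from 1.53 ± 0.0289 to 27.6 ± 6.81 CPM (log2 fold change 4.17 ± 0.20, adjusted p = 6.89e-05, edgeR, n = 2 libraries per group). dod-6 (6.21 ± 0.45, adjusted p = 0.00043), the metallothionein gene mtl-1 (8.40 ± 0.97, adjusted p = 0.00247) and the ferritin gene ftn-1 (6.72 ± 0.65, adjusted p = 0.00136) rose more. fat-5, a fatty acid desaturase (1.94 ± 0.17, adjusted p = 0.000887), and asm-2, an acid sphingomyelinase (2.03 ± 0.19, adjusted p = 0.00127), rose also. The list stood 0.51 higher in daf-2 replicate 2 than in replicate 1, and its median without replicate 2 was 1.16; mtl-1 was then 7.68. Without wild type replicate 1, dod-6 stood at 6.81, ftn-1 at 7.61 and mtl-1 at 7.63. mtl-1 stood at 9.91 without wild type replicate 2. Of 18 DAF-16-repressed genes 5 rose, 4 fell and 9 did not pass, and the list was not called (median 0.10, camera adjusted p = 0.599, median -0.07 without daf-2 replicate 2). dod-23 (-2.11 ± 0.17, adjusted p = 0.000623), dod-22 (-2.85 ± 0.47, adjusted p = 0.0105) and the peptide transporter gene pept-1 (-0.62 ± 0.09, adjusted p = 0.00741) fell, as did clec-186, a C-type lectin gene (-0.55 ± 0.13, adjusted p = 0.0301). The call of dod-22 ended without wild type replicate 1, that of pept-1 without wild type replicate 2, and that of clec-186 with any 1 of the wild-type or hel-1 libraries left out or without daf-2 replicate 2 (adjusted p = 0.0634).

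Across all genes, 1658 were higher and 990 lower in daf-2 than in wild type, of which 1036 and 144 by more than 2-fold. Without daf-2 replicate 2 the counts were 883 and 512, and 826 of the 1658 and 456 of the 990 were kept. Leaving out 1 library gave from 225 genes higher and 72 lower (without wild type replicate 2) to 3684 and 3479 (without daf-2 replicate 1), and DESeq2 gave 1446 and 1495. Of the genes that the naming rule took and that were called here, 36 were called in all 8 fits that leave out 1 library and 68 were not. H39E23.3 (at least 1005-fold), Y39G8B.7 (at least 354-fold) and the cathepsin B-like protease gene cpr-2 (at least 295-fold) had no counts in wild type. In daf-2 replicates 1 and 2 H39E23.3 had 40.2 and 141, Y39G8B.7 12 and 51.8, cpr-2 8.26 and 45 and clec-18 1.58 and 15.3 CPM; replicate 1 alone gives bounds of 445, 134, 91.6 and 17.5-fold. clec-18 (at least 93.5-fold; not called with either wild-type library left out), F47H4.2 (at least 74.2-fold) and Y20C6A.1 (at least 69.1-fold) rose from no counts likewise. Y48G8AL.20 fell to no counts (at least 65.2-fold lower). The C-type lectin genes clec-10 (-6.96 ± 0.40, adjusted p = 0.000138; -7.61 without daf-2 replicate 2) and clec-190 (-4.18 ± 0.29, adjusted p = 0.000404), the lysozyme gene ilys-5 (-4.11 ± 0.49, adjusted p = 0.00297; -4.74 without daf-2 replicate 1), ugt-53 (-3.56 ± 0.35, adjusted p = 0.0014) and acdh-2 (-3.47 ± 0.18, adjusted p = 9.67e-05) fell also.

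Several lists of stress resistance and detoxification genes rose in daf-2. Of 23 antioxidant enzymes 7 rose, 0 fell and 16 did not pass (median 0.42, camera adjusted p = 0.000108, adjusted p = 0.688 with an estimated correlation). Of 20 metal response genes 7 rose, 0 fell and 13 did not pass (median 0.59, camera adjusted p = 0.00042, adjusted p = 0.688 with an estimated correlation). Of 12 HIF-1 targets 5 rose, 0 fell and 7 did not pass (median 0.67, camera adjusted p = 0.00191, adjusted p = 0.688 with an estimated correlation). The catalase genes ctl-3 (1.32 ± 0.14, adjusted p = 0.00191) and ctl-1 (0.83 ± 0.19, adjusted p = 0.0271) rose, and ctl-1 was not called without daf-2 replicate 2 (adjusted p = 0.0753) or with any 1 of the wild-type or hel-1;daf-2 libraries left out. So did the sulfide oxidoreductase gene sqrd-1 (3.19 ± 0.36, adjusted p = 0.00225), the haem response gene hrg-7 (1.15 ± 0.13, adjusted p = 0.00207) and cdr-2 (2.02 ± 0.24, adjusted p = 0.0030). semo-1, a methanethiol oxidase gene, rose also (2.36 ± 0.48, adjusted p = 0.0192). Its value without daf-2 replicate 2 was 1.39, and it was not called with either wild-type library left out. Of 32 glutathione S-transferases 12 rose, 0 fell and 20 did not pass (median 1.03, camera adjusted p = 9.62e-05, adjusted p = 0.688 with an estimated correlation, median 0.38 without daf-2 replicate 2), with gst-39 (1.63 ± 0.20, adjusted p = 0.00303) and gst-42 (1.64 ± 0.20, adjusted p = 0.00331) examples. The medians of antioxidant, metal and HIF-1 genes without daf-2 replicate 2 were 0.28, 0.34 and 0.42. SKN-1 targets (8 of 20 higher, median 0.91, camera adjusted p = 0.00649, adjusted p = 0.697 with an estimated correlation) and cytochrome P450 genes (11 of 52 higher and 3 lower, median 0.74, camera adjusted p = 0.0169, adjusted p = 0.721 with an estimated correlation) were not called without daf-2 replicate 2 (medians 0.32 and 0.42, camera adjusted p = 0.153 and 0.234). gst-4, a standard SKN-1 target, stood at 2.59 ± 0.59, adjusted p = 0.026, and its call ended without daf-2 replicate 2 (1.68, adjusted p = 0.0829) or with either wild-type library left out. cyp-34A8 (2.06 ± 0.29, adjusted p = 0.00558; not called without wild type replicate 2) and cyp-35B1 (4.31 ± 0.60, adjusted p = 0.00557; not called without wild type replicate 1) were P450 genes that rose.

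Of 32 genes of the glyoxylate cycle, gluconeogenesis and trehalose synthesis 13 rose, 2 fell and 17 did not pass (median 0.16, camera adjusted p = 0.0021, adjusted p = 0.688 with an estimated correlation, median 0.10 without daf-2 replicate 2). The phosphoenolpyruvate carboxykinase genes pck-1 (2.78 ± 0.29, adjusted p = 0.00181) and pck-2 (1.07 ± 0.13, adjusted p = 0.00284) and the trehalose synthase gene tps-1 (1.15 ± 0.12, adjusted p = 0.00189) rose. Of 53 antimicrobial and immune effectors 16 rose, 4 fell and 33 did not pass (median 0.55, camera adjusted p = 0.0149, adjusted p = 0.737 with an estimated correlation). The list was not called without daf-2 replicate 2 (camera adjusted p = 0.191). The lysozyme gene lys-7 rose from 12 ± 0.509 to 240 ± 188 CPM (4.29 ± 0.69, adjusted p = 0.00928; 3.14 without daf-2 replicate 2, 4.89 without replicate 1, and not called with either wild-type library left out). The saposin-like genes spp-8 (1.61 ± 0.21, adjusted p = 0.00372) and spp-9 (ratio 221, interval 50.4 to 11207) rose too. Insulin-like peptide genes rose (8 of 18, median 1.31, camera adjusted p = 0.000464, adjusted p = 0.688 with an estimated correlation, median 0.60 without daf-2 replicate 2), with ins-10 from 1 count in wild type (ratio 91.6, interval 20.1 to 4541). Vitellogenins, the yolk proteins, fell as a list (1 of 6 by its own test, median -0.45, camera adjusted p = 0.0149, adjusted p = 0.688 with an estimated correlation), stood -0.79 in daf-2 replicate 2 relative to replicate 1, and were not called without it (median -0.07, camera adjusted p = 0.131).

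Collagens, hypodermis markers and body wall muscle markers rose in daf-2, and these groups stand apart in daf-2 replicate 2. Of 133 collagens 44 rose, 0 fell and 89 did not pass (74 higher and 1 lower adjusted over the list alone, median 1.40, camera adjusted p = 1.47e-10, adjusted p = 0.688 with an estimated correlation), with col-155 (0.59 ± 0.07, adjusted p = 0.00218) and col-94 (2.01 ± 0.29, adjusted p = 0.00649; not called without wild type replicate 2). Of 31 hypodermis markers 10 rose, 1 fell and 20 did not pass (median 0.93, camera adjusted p = 0.00042, adjusted p = 0.688 with an estimated correlation). Of 29 body wall muscle markers 8 rose, 0 fell and 21 did not pass (23 higher and 0 lower adjusted over the list alone, median 0.73, camera adjusted p = 1.24e-05, adjusted p = 0.688 with an estimated correlation). The medians of these 3 lists without daf-2 replicate 2 were 0.51, 0.48 and 0.24. The body wall myosin gene myo-3 rose (1.77 ± 0.37, adjusted p = 0.0206; 1.01 without daf-2 replicate 2, and not called with either wild-type library left out). Neuropeptides (14 of 80 higher, median 1.28, camera adjusted p = 2.6e-05, adjusted p = 0.721 with an estimated correlation) and neuron markers (6 of 38 higher, median 0.87, camera adjusted p = 0.00615, adjusted p = 0.721 with an estimated correlation) were not called without daf-2 replicate 2 (medians 0.30 and 0.21, camera adjusted p = 0.287 and 0.164). flp-34, an FMRFamide-like peptide gene (2.60 ± 0.29, adjusted p = 0.00207), and unc-13, which primes synaptic vesicles (1.95 ± 0.18, adjusted p = 0.00107), were called in all 8 fits that leave out 1 library. Sperm genes were not called (median 0.08, camera adjusted p = 0.864). Without daf-2 replicate 2 their median was -0.95, smaller in size than the -1.85 of wild type replicate 2 relative to replicate 1. Relative to the mean of all libraries, sperm genes stood at -0.59 in daf-2 replicate 1, 0.98 in wild type replicate 1 and -0.84 in wild type replicate 2.

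Genes of protein synthesis, folding and RNA processing fell in daf-2 by small amounts. Of 78 ribosomal protein genes 1 rose, 8 fell and 69 did not pass (2 higher and 65 lower adjusted over the list alone, median -0.36, camera adjusted p = 5.56e-16, adjusted p = 0.688 with an estimated correlation). Of 25 cytosolic chaperones 0 rose, 13 fell and 12 did not pass (median -0.49, camera adjusted p = 2.92e-08, adjusted p = 0.688 with an estimated correlation). Proteasome subunits (16 of 33 lower, median -0.33, camera adjusted p = 1.47e-10), splicing factors (16 of 48 lower and 1 higher, median -0.26, camera adjusted p = 6.54e-08) and mRNA export genes with DEAD-box helicases (12 of 39 lower and 1 higher, median -0.28, camera adjusted p = 2.92e-08) fell likewise. These 3 lists each had an adjusted p = 0.688 with an estimated correlation. Oocyte and germline genes (8 of 47 lower and 1 higher, median -0.28, camera adjusted p = 3.55e-07) and nuclear-encoded respiratory chain subunits (9 of 59 lower, median -0.13, camera adjusted p = 0.000378) did too. Both had an adjusted p = 0.688 with an estimated correlation. Without daf-2 replicate 2 the medians of these 7 lists, in the order given, were -0.19, -0.30, -0.19, -0.11, -0.16, -0.12 and -0.10. Examples are the chaperonin gene cct-3 (-0.58 ± 0.13, adjusted p = 0.026), the ribosomal gene rpl-18 (-0.45 ± 0.12, adjusted p = 0.0378), the proteasome gene rpn-3 (-0.41 ± 0.09, adjusted p = 0.0271) and the translation helicase gene inf-1 (-0.60 ± 0.14, adjusted p = 0.0291). The calls of these 4 genes ended with any 1 of the wild-type, hel-1 or hel-1;daf-2 libraries left out. The splicing factor gene rsp-5 (-0.42 ± 0.08, adjusted p = 0.0136) and the spliceosomal gene snr-2 (-0.45 ± 0.08, adjusted p = 0.0141) kept theirs except with either wild-type library left out.

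**Figure D2:**
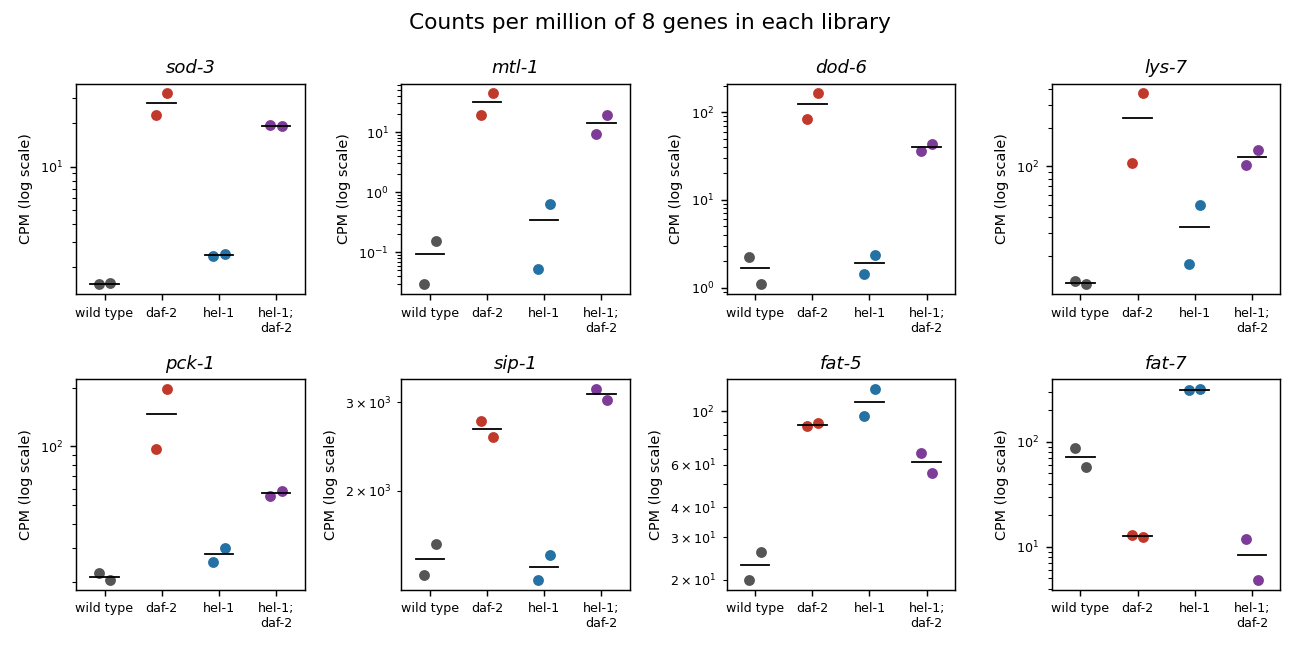
Level of 8 genes in each library in CPM, on a log axis. Bars, mean of 2 libraries. Circles, single libraries, with replicate 1 on the left and replicate 2 on the right.

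The remaining lists were not called between daf-2 and wild type: insulin/IGF-1 pathway components (5 of 23 higher, camera adjusted p = 0.656), small heat shock proteins (3 of 13 higher, 0.279), and the mitochondrial (0.0661) and endoplasmic reticulum (0.0661) unfolded protein responses. UDP-glucuronosyltransferases (0.0831), C-type lectins (0.304), fatty acid synthesis and desaturation (0.304), fatty acid breakdown and lipolysis (0.591) and autophagy and lysosome genes (0.707) were not called either. Among tissue lists these were intestine markers (0.609), pharynx markers (0.0509), gonad sheath and spermatheca markers (0.0661) and early zygotic genes of the embryo (0.0831). Histone genes (0.29) and mitochondrially encoded genes (0.173) complete them.

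In hel-1 worms 50 genes were higher and 7 lower than in wild type, fewer than in daf-2 in the fit of all libraries. Fits of only the 2 groups compared, given below, brought the counts of hel-1 and daf-2 much closer together. Fatty acid desaturases stood out: fat-5 rose 4.77-fold (2.26 ± 0.17, adjusted p = 0.00195, edgeR, n = 2 libraries per group), fat-7 4.34-fold (2.12 ± 0.32, adjusted p = 0.0469) and fat-6 1.89-fold (0.92 ± 0.13, adjusted p = 0.0327). The list of fatty acid synthesis and desaturation rose: of 25, 3 rose, 0 fell and 22 did not pass (13 higher adjusted over the list alone, median 0.35, camera adjusted p = 1.41e-14, adjusted p = 0.824 with an estimated correlation). Other genes with large rises were Y41C4A.32 (6.26 ± 0.33, adjusted p = 0.000351), from 2.73 ± 1.8 to 208 ± 9.54 CPM (7.16 without wild type replicate 2), the ARF-family gene warf-1 (5.68 ± 0.22, adjusted p = 4.22e-05), B0205.13 (3.83 ± 0.29, adjusted p = 0.00208) and F22B8.7 (3.76 ± 0.23, adjusted p = 0.000696). cdr-4, a cadmium response gene (2.88 ± 0.32, adjusted p = 0.0174), and tbb-6, a beta-tubulin gene (2.87 ± 0.30, adjusted p = 0.0129), rose also and were not called without hel-1 replicate 2 or with either wild-type library left out. Y102A5C.6 (-3.47 ± 0.23, adjusted p = 0.000852), Y102A5C.5 (-3.30 ± 0.24, adjusted p = 0.00177) and F02E9.10 (-1.97 ± 0.07, adjusted p = 3.02e-05) fell. tcl-2 (-1.1 ± 0.16, adjusted p = 0.0426), F42A9.6 (-0.81 ± 0.11, adjusted p = 0.0289) and C05D12.3 (-0.62 ± 0.08, adjusted p = 0.0289) fell less, and their calls ended with any 1 of the wild-type, hel-1 or hel-1;daf-2 libraries left out. fat-7 was not called with any 1 of the wild-type or hel-1 libraries left out, nor fat-6 without hel-1 replicate 2 or with any 1 of the wild-type or hel-1;daf-2 libraries left out.

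Collagens rose in hel-1 as a list, with no member past its own test (0 of 133, median 0.88, camera adjusted p = 7.57e-12, adjusted p = 0.824 with an estimated correlation). So did neuropeptides (1 of 80, 8 adjusted over the list alone, median 0.83, camera adjusted p = 1.28e-09, adjusted p = 0.824 with an estimated correlation) and neuron markers (0 of 38, median 0.49, camera adjusted p = 0.000154, adjusted p = 0.824 with an estimated correlation). Collagens stood -0.62 in wild type replicate 2 relative to replicate 1. DAF-16-activated genes rose a little: of 39, 1 rose, 0 fell and 38 did not pass (median 0.38, camera adjusted p = 0.000154, adjusted p = 0.824 with an estimated correlation), the riser being fat-5. The list stood 0.51 higher in hel-1 replicate 2 than in replicate 1. DAF-16-repressed genes stood at 0.33 (camera adjusted p = 0.155). Intestine markers (2 of 28 higher, median 0.22, camera adjusted p = 0.000154, adjusted p = 0.824 with an estimated correlation) and immune effectors (0 of 53 higher, median 0.43, camera adjusted p = 0.000312, adjusted p = 0.824 with an estimated correlation) rose too, and stood 0.37 and 0.47 higher in hel-1 replicate 2 than in replicate 1. Examples are the intestinal acid phosphatase gene pho-1 (0.50 ± 0.07, adjusted p = 0.0432), the neuropeptide gene nlp-20 (1.49 ± 0.15, adjusted p = 0.011) and the small heat shock gene hsp-17 (1.40 ± 0.21, adjusted p = 0.0491). nlp-20 was not called with any 1 of the wild-type or hel-1 libraries left out, and pho-1 and hsp-17 were called only in the fits that left out a daf-2 library. Oocyte and germline genes (median -0.17, camera adjusted p = 2.47e-08, adjusted p = 0.824 with an estimated correlation) and proteasome subunits (median -0.14, camera adjusted p = 5.13e-07, adjusted p = 0.824 with an estimated correlation) fell as lists, with 0 of 47 and 0 of 33 members past their own edgeR test; edgeR's count over all genes at an unadjusted p under 0.05 was 1674. Leaving out 1 library gave from 6 genes higher and 3 lower (without wild type replicate 1) to 411 higher (without daf-2 replicate 2) and 95 lower (without daf-2 replicate 1), and DESeq2 gave 206 and 31. Of 18 named results called, 8 were called in all 8 fits.

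In hel-1;daf-2 worms 2 genes were higher and 5 lower than in daf-2. sax-2, needed to keep neurons in shape, rose (1.45 ± 0.11, adjusted p = 0.0142, edgeR, n = 2 libraries per group). It had 172 ± 18.4 CPM in wild type, 61.4 ± 4.85 in daf-2 and 167 ± 14.2 in hel-1;daf-2. F13H8.8 rose from 1.3 ± 0.14 to 9.25 ± 2.84 CPM (2.83 ± 0.31, adjusted p = 0.044). The autophagy receptor gene sqst-1 fell (-0.95 ± 0.10, adjusted p = 0.0269), from 59 ± 6.53 to 30.5 ± 0.485 CPM. nlp-20 (-1.58 ± 0.16, adjusted p = 0.0269), C08F11.7 (-3.05 ± 0.34, adjusted p = 0.044), saeg-1 (-1.29 ± 0.12, adjusted p = 0.0269) and ctg-1 (-0.85 ± 0.08, adjusted p = 0.0269) fell also. None of these 7 calls held in all 8 fits that leave out 1 library. Those of F13H8.8 and nlp-20 ended without daf-2 replicate 2 (adjusted p = 0.16 and 0.0528). All 7 ended with any 1 of the hel-1 or hel-1;daf-2 libraries left out, and all but sax-2 with either wild-type library left out.

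As a group, DAF-16-activated genes fell in hel-1;daf-2 relative to daf-2: of 39, 0 rose, 0 fell and 39 did not pass (7 lower adjusted over the list alone, median -0.52, camera adjusted p = 1.67e-06, adjusted p = 0.775 with an estimated correlation). sod-3 had 19.3 ± 0.20 CPM in hel-1;daf-2 and 27.6 ± 6.81 in daf-2, dod-6 39.8 ± 5.65 and 124 ± 57.6, and lys-7 118 ± 22 and 240 ± 188, none of them called. The daf-2 libraries stood far apart in lys-7, and replicate 1 lay below the mean of hel-1;daf-2. The members that the naming rule takes here, as the best expressed, were sip-1, a small heat shock gene (0.23 ± 0.13, adjusted p = 0.341), and lea-1. Without daf-2 replicate 2, sip-1 stood at 0.18 and lea-1 at -0.03. Without daf-2 replicate 2 the list's median was -0.22 (camera adjusted p = 0.000982, adjusted p = 0.981 with an estimated correlation). HIF-1 targets fell (0 higher and 0 lower of 12, 7 lower adjusted over the list alone, median -0.51, camera adjusted p = 1.74e-06, adjusted p = 0.775 with an estimated correlation, median -0.23 without daf-2 replicate 2). Collagens (median -1.13, camera adjusted p = 2e-17), neuropeptides (median -1.32, camera adjusted p = 1.48e-11), neuron markers (median -0.94, camera adjusted p = 8.3e-09), hypodermis markers (median -0.81, camera adjusted p = 6.27e-08) and body wall muscle markers (median -0.72, camera adjusted p = 1.48e-11) fell as lists. Each of these 5 had an adjusted p = 0.775 with an estimated correlation, the members past their own test were 0, 1, 0, 0 and 0, and the medians without daf-2 replicate 2 were -0.25, -0.11, -0.28, -0.42 and -0.18. Pharynx markers (median -2.08, camera adjusted p = 4.85e-05, adjusted p = 0.775 with an estimated correlation) and sperm genes (median -1.21, camera adjusted p = 1.28e-06, adjusted p = 0.775 with an estimated correlation) were not called without daf-2 replicate 2 (medians -0.18 and -0.11, camera adjusted p = 0.152 and 0.774). Ribosomal proteins (median 0.17, camera adjusted p = 2.41e-11, adjusted p = 0.775 with an estimated correlation) and oocyte and germline genes (median 0.19, camera adjusted p = 3.61e-10, adjusted p = 0.775 with an estimated correlation) rose as lists. Their medians without daf-2 replicate 2 were 0.03 and 0.06.

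Over all genes, 2307 were under an unadjusted edgeR p of 0.05 between hel-1;daf-2 and daf-2 (550 higher and 1757 lower). DESeq2 called 13 higher and 221 lower, and no filter 28 and 582. A fit of daf-2 and hel-1;daf-2 alone called 0 and 0. Leaving out 1 library gave from 0 and 0 (without hel-1 replicate 1) to 3050 and 2762 (without daf-2 replicate 1).

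Between hel-1 and hel-1;daf-2, 406 genes were higher and 364 lower in the double mutant. They include the chromosome V genes set out below, which may differ with the strain. Of the DAF-16-activated genes 12 rose, 1 fell and 26 did not pass (19 and 5 adjusted over the list alone, median 0.46, camera adjusted p = 5.05e-09, adjusted p = 0.958 with an estimated correlation). sod-3 rose 7.96-fold (2.99 ± 0.19, adjusted p = 0.000291, edgeR, n = 2 libraries per group), with dod-6 (4.40 ± 0.43, adjusted p = 0.00184), ftn-1 (5.05 ± 0.65, adjusted p = 0.00582), mtl-1 (5.48 ± 0.81, adjusted p = 0.0104) and sip-1 (1.14 ± 0.13, adjusted p = 0.00311). mtl-1 was not called without hel-1 replicate 1 or hel-1;daf-2 replicate 2, nor sip-1 without hel-1 replicate 1 or hel-1;daf-2 replicate 1. The value of mtl-1 was 4.52 without hel-1 replicate 1, 7.99 without hel-1 replicate 2 and 4.83 without hel-1;daf-2 replicate 2. That of ftn-1 was 4.37 and 6.12 without hel-1 replicates 1 and 2. It was 4.26 without hel-1;daf-2 replicate 1. DAF-16-repressed genes as a list had median -0.05, camera adjusted p = 0.382, and dod-22 (-4.87 ± 0.47, adjusted p = 0.0018; -5.68 without hel-1;daf-2 replicate 2) and dod-23 (-1.40 ± 0.17, adjusted p = 0.0043) fell. Antioxidant enzymes rose (4 of 23 higher and 1 lower, median 0.08, camera adjusted p = 0.0025, adjusted p = 0.958 with an estimated correlation), ctl-3 among them (1.51 ± 0.14, adjusted p = 0.00172). Fatty acid synthesis and desaturation fell (4 of 25 lower, median -0.36, camera adjusted p = 6.87e-07, adjusted p = 0.958 with an estimated correlation). fat-7 went from 313 ± 6.96 CPM in hel-1 to 8.35 ± 5.02 in hel-1;daf-2 (-5.22 ± 0.38, adjusted p = 0.00057; -6.03 without hel-1;daf-2 replicate 1), and fat-5 (-0.84 ± 0.16, adjusted p = 0.0264) fell too, the latter not called without hel-1 replicate 2 or with either hel-1;daf-2 library left out. Neuropeptides (7 of 80 lower, median -0.54, camera adjusted p = 0.00017, adjusted p = 0.958 with an estimated correlation) and neuron markers (5 of 38 lower, median -0.48, camera adjusted p = 0.000995, adjusted p = 0.958 with an estimated correlation) fell, with nlp-20 (-2.39 ± 0.16, adjusted p = 0.00032) and the touch neuron gene mec-17 (-1.86 ± 0.25, adjusted p = 0.00711; not called without hel-1;daf-2 replicate 2).

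Among genes with at least 5 CPM in the higher group, large rises between hel-1 and hel-1;daf-2 were those of C18D4.6 (at least 62.4-fold), Y20C6A.1 (at least 60-fold) and the F-box gene fbxb-7 (at least 59.4-fold), with no counts in hel-1, and lsy-27 (ratio 1357, interval 305 to 67280). icmt-1, an isoprenylcysteine methyltransferase gene (8.14 ± 0.25, adjusted p = 9.44e-06), and R05H10.7 (7.75 ± 0.51, adjusted p = 0.000321; 8.58 without hel-1 replicate 1) rose as well. Y41C4A.32 (-7.72 ± 0.37, adjusted p = 5.97e-05), warf-1 (-6.56 ± 0.23, adjusted p = 9.88e-06), B0205.13 (-5.61 ± 0.34, adjusted p = 0.000245), clec-10 (-5.25 ± 0.35, adjusted p = 0.00032; -5.85 without hel-1;daf-2 replicate 1) and clec-47 (-4.09 ± 0.20, adjusted p = 6.63e-05) fell. Leaving out 1 library gave from 76 genes higher and 73 lower (without hel-1;daf-2 replicate 2) to 1195 and 1077 (without daf-2 replicate 2), and a fit of the 2 groups alone gave 1410 and 1499. Of 46 named results called, 20 were called in all 8 fits.

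Genes on 1 stretch of chromosome V, set out after their values were seen, had nearly all of their counts in the daf-2 strains. Between bases 17339084 and 17379233 (40.1 kb), 8 genes were called higher both in daf-2 and in hel-1;daf-2: F47H4.7, fbxa-188, fbxa-189, lsy-27, F47H4.2, F47H4.12, Y20C6A.1 and fbxb-7, F-box genes among them. Of the 11 annotated genes of the stretch with counts in the daf-2 strains, 10 had 0 counts in all 4 wild-type and hel-1 libraries. The stretch had 6400 counts in the 4 daf-2 and hel-1;daf-2 libraries and 2 in the others. All 7 tested genes within 100 kb on either side had more than 3 counts over the wild-type and hel-1 libraries.

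**Figure D3:**
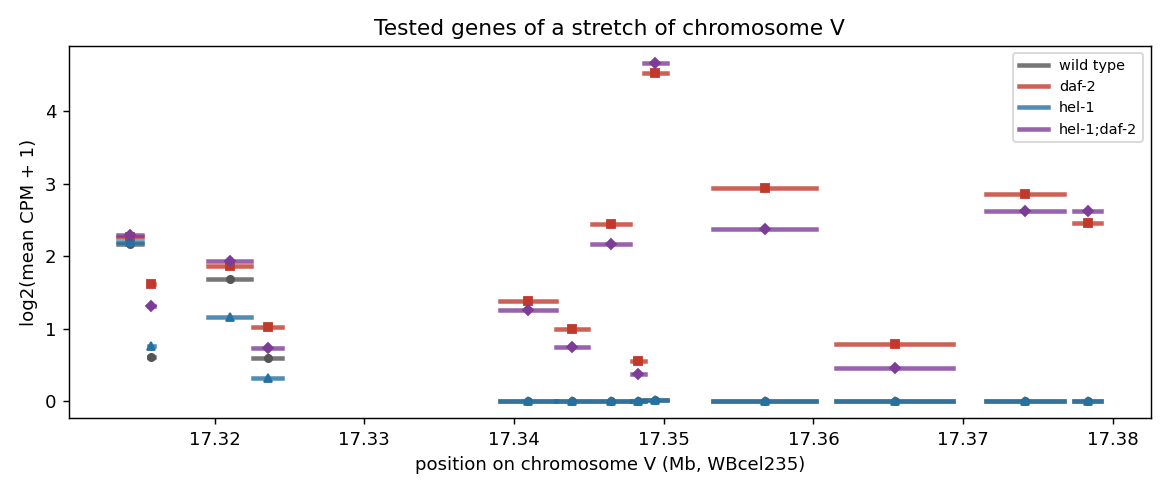
Mean level, as log2 of CPM plus 1, of the tested genes in and beside the stretch of chromosome V, by position in Mb, in the 4 genotypes. At 0, the symbols of hel-1 cover those of wild type.

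Over the 2648 genes called between daf-2 and wild type, the daf-2 effect in the hel-1 background kept the sign in 75.7%, and the slope of the effect in hel-1 on that in wild type was 0.49 (median ratio 0.29). The slope was 0.43 for genes higher in daf-2 and 0.82 for those lower (median ratios 0.22 and 0.37). Over all 13722 tested genes it was 0.30, with 48.7% of signs kept. Genes were chosen here on 1 of the 2 comparisons, which lowers a slope by itself; over the 770 genes called in the hel-1 background the slope the other way was 0.86 (1.13 for genes higher, 0.55 for those lower), with 79.5% of signs kept. For the 39 DAF-16-activated genes, not chosen on these libraries, the slope of the effect in hel-1 on that in wild type was 0.62, and for the 18 DAF-16-repressed genes 0.49. Of genes higher in daf-2, 262 were also higher in the hel-1 background (49.1 expected if independent), and 116 were lower in both (26.3 expected). The slope over the 2648 genes was between 0.22 (without daf-2 replicate 1) and 0.70 (without wild type replicate 2) when 1 library was left out.

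**Figure D4:**
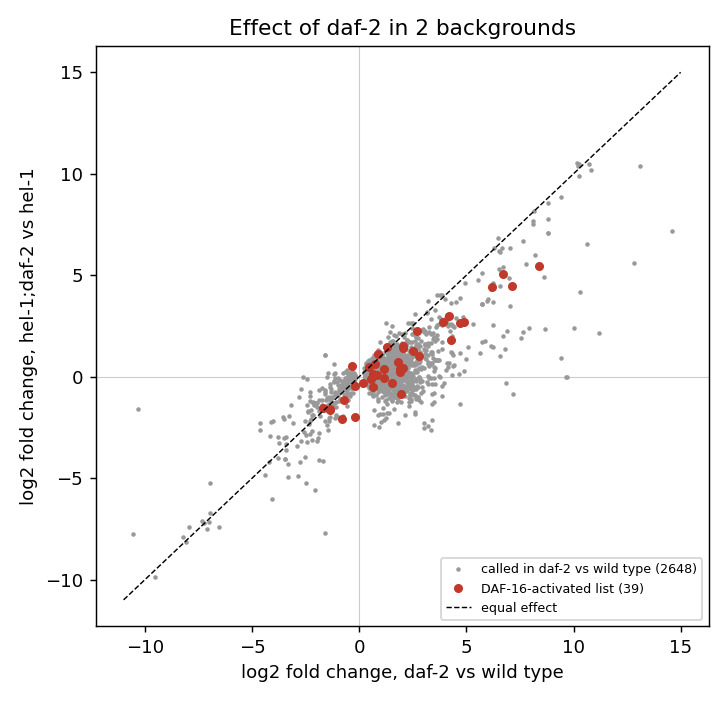
Log2 fold change of the daf-2 mutation in the hel-1 background against that in the wild-type background, for the 2648 genes called in daf-2 and the 39 DAF-16-activated genes. Dashed line, equal effects.

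The interaction, which tests whether the hel-1 effect differs between the 2 daf-2 backgrounds, was called in 113 genes: 10 above 0 and 103 below. All 103 had a hel-1 effect above 0 in the wild-type background and 99 an effect below 0 in the daf-2 background. Of these genes 32 were called in the first and 5 in the second. Choosing genes on the difference of the 2 effects favours such signs by itself. fat-5 is an example: 23 ± 4.38 CPM in wild type, 110 ± 19.9 in hel-1, 88.2 ± 2.29 in daf-2 and 61.4 ± 8.22 in hel-1;daf-2 (log2 -2.78 ± 0.23, adjusted p = 0.00565, edgeR, n = 2 libraries per group). warf-1 (-5.91 ± 0.36, adjusted p = 0.00137), F22B8.7 (-3.87 ± 0.29, adjusted p = 0.00338) and nlp-20 (-3.07 ± 0.22, adjusted p = 0.00244) were below 0 and F02E9.10 (2.16 ± 0.09, adjusted p = 0.000171) above it, and these 5 were called in all 8 fits that leave out 1 library. fat-5 starts at base 17725004 of chromosome V, inside the window, set out under other observations, where 14 genes were on in the daf-2 strains. Its levels were not separated from differences between the strains. Y41C4A.32 (-6.12 ± 0.70, adjusted p = 0.0184) was not called without daf-2 replicate 2 (adjusted p = 0.0613), hel-1 replicate 2 or with either hel-1;daf-2 library left out. It stood at -7.0 without wild type replicate 2. Of the 57 genes called between hel-1 and wild type, 21 had the same sign in the daf-2 background, 0 were called there with that sign by edgeR and 2 were called with the opposite sign. Over all tested genes the hel-1 effects in the 2 backgrounds correlated at r = -0.42, and at -0.15 without daf-2 replicate 2. Whole lists, collagens and neuropeptides among them, rose in hel-1 and fell in hel-1;daf-2 against daf-2. The genes counted by sign next are therefore not separate signals. Among the 472 genes with an unadjusted p under 0.05 in both backgrounds, 23 had the same sign and 449 the opposite; without daf-2 replicate 2 these were 59 and 329 of 388.

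Neuropeptides had an interaction below 0 as a list (5 of 80 called, 37 adjusted over the list alone, median -2.40, camera adjusted p = 1.52e-13, adjusted p = 0.711 with an estimated correlation, median -0.82 without daf-2 replicate 2). So did collagens (3 of 133 called, median -1.95, camera adjusted p = 1.08e-18, adjusted p = 0.711 with an estimated correlation, -1.19 without daf-2 replicate 2). DAF-16-activated genes (1 of 39 called, 7 adjusted over the list alone, median -1.15, camera adjusted p = 1.45e-06, adjusted p = 0.711 with an estimated correlation, -0.70 without it) were below 0. Fatty acid synthesis and desaturation was too (2 of 25 called, median -0.48, camera adjusted p = 1.72e-07, adjusted p = 0.711 with an estimated correlation). DAF-16-repressed genes had median -0.80, camera adjusted p = 0.862. Their median was -0.14 without daf-2 replicate 2. Oocyte and germline genes were above 0 (median 0.37, camera adjusted p = 1.36e-11, adjusted p = 0.711 with an estimated correlation, 0.20 without daf-2 replicate 2). Leaving out 1 library gave from 1 gene above 0 and 6 below (without wild type replicate 2) to 3523 and 3141 (without daf-2 replicate 1), and DESeq2 gave 41 and 550.

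The comparisons of daf-2 with wild type and of hel-1;daf-2 with daf-2 share the daf-2 libraries, which ties their fold changes together. Among called genes, 5 were higher in the first and lower in the second (C08F11.7, nlp-20, saeg-1, sqst-1 and ctg-1), where 40 simulations of unchanged groups gave a mean of 0 and independent lists of these sizes would share 0.604. A further 1 (sax-2) was lower and then higher (0.025 in simulations and 0.144 if independent). The simulations hold no effects and the independent lists no shared libraries, so neither gives the overlap expected here. The correlation of the 2 fold changes over all genes was -0.57 against -0.49 in the simulations, and the covariance -0.378 against -0.077.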

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

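The tests of explanations in the next 2 paragraphs were chosen after the results they bear on were seen. The results below were set apart because the hel-1 effect differed between the 2 daf-2 backgrounds by edgeR's test of the interaction: 10 genes above 0 and 103 below, and 23 gene lists by camera, of which 0 were kept with an estimated correlation. Values are interaction log2 fold changes. Among lipid genes and DAF-16 targets these were fat-5 (-2.78) and fat-6 (-1.11). Among neuron and neuropeptide genes they were unc-13 (-1.95), mec-17 (-2.95), mec-7 (-2.76), nlp-20 (-3.07), nlp-12 (-2.57), nlp-43 (-3.75), flp-15 (-3.26) and flp-7 (-3.04). Collagens were col-34 (-3.22), col-153 (-2.34) and col-118 (-1.42), and UDP-glucuronosyltransferases ugt-19 (-2.02), ugt-50 (-1.20) and ugt-2 (-2.10). Other genes below 0 were Y41C4A.32 (-6.12), warf-1 (-5.91), B0205.13 (-3.52), F22B8.7 (-3.87), cdr-4 (-3.28), tbb-6 (-3.17), dlhd-1 (-4.76), F45D11.14 (-4.65), C08F11.7 (-4.1), saeg-1 (-1.58), sqst-1 (-2.15), ctg-1 (-1.01) and clec-47 (-2.21). Those above 0 were F13H8.8 (2.70), Y102A5C.6 (2.54), Y102A5C.5 (2.31), F02E9.10 (2.16), kin-35 (1.83), sax-2 (1.46), F42A9.6 (1.05) and C05D12.3 (0.76). The calls of F13H8.8, Y41C4A.32, B0205.13, dlhd-1, ugt-2, col-153 and flp-15 ended without daf-2 replicate 2 (adjusted p = 0.060, 0.0613, 0.106, 0.0606, 0.056, 0.0543 and 0.0559). With 1 library left out, 4 of the 37 values moved by over 1.5 times: Y41C4A.32 to -7.0 (wild type replicate 2), dlhd-1 to -5.36 and -3.77 (hel-1 replicates 1 and 2), and F45D11.14 to -4.0 and nlp-43 to -3.07 (daf-2 replicate 2). Of the 37 genes, 6 were called in all 8 fits that leave out 1 library.

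DAF-16-activated genes were lower in hel-1;daf-2 than in daf-2. If daf-2 replicate 2 alone gave this, the list's median without that library would lie at 0; it was -0.22 (bootstrap interval over 39 genes -0.35 to -0.03). The list differed by up to 0.51 between replicates of a genotype, more than that value, so this is left open. If hel-1;daf-2 worms held less somatic RNA, hypodermis and intestine markers were taken to fall alike. Without daf-2 replicate 2 the hypodermis median minus the intestine median was -0.41 (interval -0.70 to -0.20, n = 59 markers), but it differed by up to 0.46 between replicates. In daf-2 replicate 2 relative to replicate 1, hypodermis markers stood at 0.39, intestine markers at 0.01 and oocyte and germline genes at -0.30. The 2 marker lists thus need not move alike, which leaves a lower share of somatic RNA open too. If hel-1 acted alike in both backgrounds, the list's median in hel-1 against wild type would be near -0.52. It was 0.38 (interval 0.17 to 0.60, n = 39 genes) and 0.01 to 0.89 over the 4 pairs of single libraries, which argues against an effect of that size. Set against the -0.22 found without daf-2 replicate 2, the gap of up to 0.51 between replicates leaves a smaller shared effect open.

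As a group, genes changed between hel-1 and wild type did not move in that direction between daf-2 and hel-1;daf-2. With a hel-1 effect of the same size in both backgrounds, their median effect in the daf-2 background, signed by their direction in hel-1, would be near 1.20. That value is raised by choosing the genes on the same comparison. Over 57 genes the median was -0.12 (bootstrap interval over genes -0.22 to -0.00386), and from -0.16 to -0.01 over the 4 pairs of single libraries. These values restate the pattern, in libraries that did not choose the genes. They argue against an effect of the same size for these genes as a group. A block of linked variants in the hel-1 strain that acts on the genes within it is excluded for most of them, since 35 of the 57 lie outside the chromosome that holds most, V; for a few it was looked for as a cluster: with neighbours within 50 kb counted once, the fullest 1 Mb window held 3 genes (median of 10000 random sets 3, 95th percentile 5, permutation p = 0.994). Counted singly, as was done later to match the test on the daf-2 strains, it held 6 (median 4, 95th percentile 5, permutation p = 0.0216): Y102A5C.36, Y102A5C.5, Y102A5C.6, fbxa-192, fat-5 and pgp-9 on chromosome V. The 2 counts differ, so a block behind a few of these genes is left open, as is a hel-1 effect that depends on daf-2 function. Counts in windows show only clusters and cannot show single variants scattered over the genome. Strain and hel-1 genotype change together in these libraries, so other differences of the hel-1 strain are left open as well.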

How the results depend on the processing

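Of 325 named results, 310 kept their side of the threshold and direction with DESeq2, 320 with RLE size factors, 310 without a filter, 294 with the filter of 1 CPM in 4 libraries (whose lower-expressed genes have no value there) and 312 with the replicate block. Fits of only the 2 groups compared give no interaction, so those results have no value there. In these fits 193 kept theirs, 66 lost their call and 2 gained one. With 1 library left out, 216 to 301 kept theirs. Where no other cause is given below, the cause was not tested.

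DESeq2 called 1495 genes lower in daf-2, 206 higher and 31 lower in hel-1, 13 higher and 221 lower in hel-1;daf-2 than in daf-2, 41 interactions above 0 and 550 below, and 179 genes called in opposite directions in daf-2 (against wild type) and hel-1;daf-2 (against daf-2), where the fit used throughout gave 6. Its median log2 fold change over all genes was 0.01 in daf-2 where edgeR gave 0.10, and 0.02 where edgeR gave -0.09 in the interaction. RLE size factors gave 11 genes lower in hel-1 and 4 higher in hel-1;daf-2 than in daf-2. With no filter the counts were 321 and 40 in hel-1, 28 and 582 in hel-1;daf-2 against daf-2, 670 lower against hel-1, 74 and 1141 in the interaction, and 486 opposite calls. The filter of 1 CPM gave 1 and 3 in hel-1;daf-2 against daf-2. Fits of only the 2 groups compared gave 347 and 77 in daf-2 and 184 and 29 in hel-1. They gave 0 and 0 in hel-1;daf-2 against daf-2 and 1410 and 1499 against hel-1. Calls thus dropped in daf-2 and increased in hel-1 and in hel-1;daf-2 against hel-1. The fit used throughout shares its spread over the 4 groups. The daf-2 libraries stood furthest apart (standard deviation of the log2 difference 0.446, with 0.258 in wild type, 0.221 in hel-1 and 0.183 in hel-1;daf-2). The fits in which calls increased hold no daf-2 library. Counts of calls in hel-1 and daf-2 therefore do not compare the sizes of the 2 effects. What share of the shift this gives was not tested. Over the genes called in hel-1;daf-2 against hel-1, the slope of the daf-2 effect in the hel-1 background on that in wild type was 0.84.

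Of the lists called by camera, 0 were kept with an estimated correlation in each of the 5 comparisons, and fry called 1 in daf-2 (respiratory chain subunits) and 0 in each of the others. Mitochondrially encoded genes in hel-1;daf-2 against daf-2 had a median of 0.25, and of -0.11 (without hel-1;daf-2 replicate 2, camera adjusted p = 0.780) to 0.59 (without daf-2 replicate 2) with 1 library left out.

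A block for the replicate number gave 9 genes lower in hel-1;daf-2 than in daf-2 and 10 opposite calls. The log2 differences between replicates 1 and 2 correlated between genotypes at -0.46 (wild type and daf-2) to 0.17 (wild type and hel-1), so the numbers do not mark pairs.

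Leaving out 1 library leaves fewer residual degrees of freedom, but it moved counts both up and down, and the cause was not tested. It gave 225 to 3684 genes higher and 72 to 3479 lower in daf-2, 6 to 411 and 3 to 95 in hel-1, 0 to 3050 and 0 to 2762 in hel-1;daf-2 against daf-2, 76 to 1195 and 73 to 1077 against hel-1, and 1 to 3523 and 6 to 3141 in the interaction. The lists called were 18 to 29, 14 to 25, 16 to 28, 11 to 15 and 18 to 27 in the same order, the slope 0.22 to 0.70 and the opposite calls 0 to 4796. The highest counts of daf-2 against wild type, of hel-1;daf-2 against daf-2 and of the interaction came without daf-2 replicate 1, where replicate 2 stands alone for daf-2. Genes that did not pass filterByExpr were not tested. With 2 libraries per group, edgeR recovered a 2-fold change in 27 to 36 of 50 simulated genes, depending on the comparison laid out.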

Other observations

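The tests on the 39 genes of the next paragraph were chosen after the results they bear on were seen. Metal response genes rose in hel-1;daf-2 against hel-1 (3 of 20 higher and 1 lower, median 0.39, camera adjusted p = 0.0406, adjusted p = 0.958 with an estimated correlation), hrg-7 among them (0.92 ± 0.13, adjusted p = 0.00752; not called without hel-1 replicate 2 or hel-1;daf-2 replicate 2), and the list was not called without daf-2 replicate 2 (camera adjusted p = 0.119). SKN-1 targets rose in the same comparison (0 of 20 over all genes, 7 adjusted over the list alone, median 0.43, camera adjusted p = 0.00699, adjusted p = 0.958 with an estimated correlation), as did glutathione S-transferases (2 of 32 higher and 1 lower, median 0.28, camera adjusted p = 0.00599, adjusted p = 0.958 with an estimated correlation), with gst-39 (1.42 ± 0.20, adjusted p = 0.0077; not called without hel-1 replicate 1 or hel-1;daf-2 replicate 2). UDP-glucuronosyltransferases had an interaction below 0 (3 of 55 called, median -0.48, camera adjusted p = 0.0475, adjusted p = 0.763 with an estimated correlation) that was not called without daf-2 replicate 2 (median -0.15, camera adjusted p = 0.331).

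Over the 39 genes with a log2 fold change of at least 5 in size, called both in daf-2 and in hel-1;daf-2 against hel-1, 27 were on in the daf-2 strains and 12 off, and 20 lie on chromosome V, 9 on I, 5 on II, 3 on IV and 2 on III. As a hypothesis, several blocks of linked variants that differ between the daf-2 strains and the others would put them in clusters: with neighbours within 50 kb counted once, the fullest 1 Mb window held 4 (median of 10000 random sets 3, 95th percentile 4, permutation p = 0.167), which leaves it open. A hypothesis of 1 differing stretch of chromosome V for part of them, with the same genes counted singly only after that output was seen, gave 14 in 1 window (median 3, 95th percentile 4, permutation p = 0.0001, the smallest 10000 draws can give). Co-regulated neighbouring copies could give the same. These 14 genes lie between bases 17339084 and 17904329, and fbxa-192, fat-5 and pgp-9 of the hel-1 window lie between the same bases. Activation by DAF-16 predicts more members of its list among the 27 than among the rest of the 262 genes called higher in both comparisons: there were 2, ftn-1 and mtl-1, and 10 among the rest (Fisher's exact p = 0.356), which leaves it open. Among the 39 genes, clec-15 is counted under more than 1 identifier with the same levels in each (1.61 CPM in daf-2 and 0.49 in hel-1;daf-2). The 39 are therefore not all separate signals. The strain changes together with the daf-2 genotype, and with the hel-1 genotype, in these libraries, and the sequence of the strains was not analysed here.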
